A study of Xenopus laevis and Mus musculus with 9 samples.

How the data were processed

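The series holds 9 chromatin immunoprecipitation sequencing (ChIP-seq) libraries. In this assay protein is crosslinked to DNA, the chromatin is sheared, and the DNA bound by one protein is pulled down with an antibody and sequenced. Antibodies were against Smc3, a core subunit of the ring-shaped cohesin complex (7 libraries), or against CTCF, the DNA-binding protein at which cohesin is known to stop in mammalian cells (2 libraries). The material was frog (Xenopus laevis) pronuclei formed from sperm in egg extract (5 libraries), the frog cell line XL177 (1 library) and mouse embryonic fibroblasts (3 libraries, all Smc3). The processed data used here were those of the fibroblasts, and the 6 frog libraries were not analysed here, so no group was compared with another.

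The fibroblast data were 1 list of genomic regions. Per the file headers, the authors made it with MULTOVL as the union of 3 separate peak lists in narrowPeak form, joining peaks that share at least 1 bp and keeping every region that holds a peak of at least 1 list. The score that the authors deposited with each region is the largest number of lists that overlap at one position, from 1 to 3. It is not a peak height. In the deposited list each region also carries other fields, namely its start and end and, for each peak in it, the list, start and end. No height, fold enrichment, p-value or read count per peak was used, so the depth behind the peaks is unknown here and no interval that needs it is given. Per the submitters' processing notes, Bowtie 1.2.2, MACS 1.4.2 and MACS2 2.2.5 and the mouse build mm9 were used in the series. Which caller and threshold gave each of the 3 lists, and which control library was used, are not given in the sources used here. All coordinates below are mm9 as named in those notes, counted from 1.

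The labels give 3 fibroblast replicates and the file headers give 3 peak lists, but no label ties a list to a replicate number. The lists are called list 1, list 2 and list 3 in the order of the file headers. They were taken as 1 list per library, and a mean ± SD with n = 3 is over lists. Nothing in the labels says whether the libraries came from separate cultures, so that spread may be technical. The number of peaks of each list equalled the number in the file headers, every region spanned exactly its outermost peaks, and no region overlapped another. A region was assigned to a list when it held at least 1 peak of it. The score was lower than that number of lists in 62 regions, where peaks of the 3 lists were joined in a chain without a common base.

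From the list were computed region widths, distances between the midpoints of neighbouring regions, regions per Mb of each chromosome and regions per 1 Mb window on a fixed grid. Density used the span from the first to the last region of a chromosome, because an assembled length of the build was not used here. Spacing and clustering were set against 1000 uniform random placements of the same number of midpoints within each chromosome. For clustering only, these placements gave a one-sided simulation p. The density of X was tested by its distance from the median density of the 20 chromosomes, as the share of chromosomes at least as far from it in either direction, an exact two-sided p whose smallest possible value is 0.05. Overlap between lists was set against 100 draws in which each peak of the second list was moved by 10 to 100 kb in either direction. Shares carry 95% Wilson intervals, which cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The code was tested on simulated data with known answers: 59727 simulated regions gave 7607 in all 3 lists for 7607 simulated, and an X to autosome ratio of 0.300 for 0.3 simulated. These tests check the counting only. The simulated sites were spaced so that different sites could not touch, and the number placed on each chromosome fixed the ratio.

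The numbers, widths, spacing, X density and clustering of regions, the relation of score to width, the naming rule and the alternatives not named as added were chosen before the data were examined. The comparisons between lists, the set of regions in all 3 lists and the overdispersion were added after seeing the data. The rule named the 5 widest regions, the 5 windows of 1 Mb with the most regions and the 5 longest gaps. It also asked for the 10 regions with the highest score and the highest of each chromosome, which could not be picked because 16450 regions tie at the highest score of 3. Positions relative to genes, a search for the CTCF motif and gene lists had been planned only for the case that sequence or annotation of the build was used. They were not run, and no gene is named. The planned threshold at the median score removed nothing, since that median is 1, and thresholds of 2 and of 3 lists were added after seeing the data. The other alternatives were merging of regions within 1 kb, edge-to-edge distances, a limit of 5 kb on width, windows of 200 kb and 5 Mb, empty windows left out, and each list left out in turn.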

Results

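Binding of the cohesin subunit Smc3 was mapped by ChIP-seq in mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos, in 3 libraries. The series also lists Smc3 or CTCF libraries of frog pronuclei after 140 min in egg extract, without added CTCF or with recombinant CTCF at 50 nM or 123 nM, and an Smc3 library of the frog cell line XL177. Each of these frog groups has 1 library, and none was analysed here. The series title concerns cohesin and CTCF in the folding of frog sperm and pronuclear chromatin. The comparisons below are therefore those within the fibroblasts: between the 3 peak lists, between regions shared by the lists and regions of 1 list, between observed and random positions, and between X and the autosomes.

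The 3 lists held 111085 Smc3 peaks, which formed 64280 regions covering 19.4 Mb of the genome. List 1 had 36070 peaks, list 2 had 19321 and list 3 had 55694, or 37028 ± 18205 peaks (SD, n = 3). The longest list was thus 2.88 times the shortest. A core of 16512 regions, 25.7% of all (95% Wilson interval 25.4 to 26.0%), held peaks of all 3 lists. Another 11243 regions (17.5%) held peaks of 2 lists, and 36525 (56.8%) held peaks of 1 list. Most of the regions of 1 list came from list 3, with 29306, against 6922 from list 1 and 297 from list 2. The union without list 3 held 36696 regions.

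**Figure D1:**
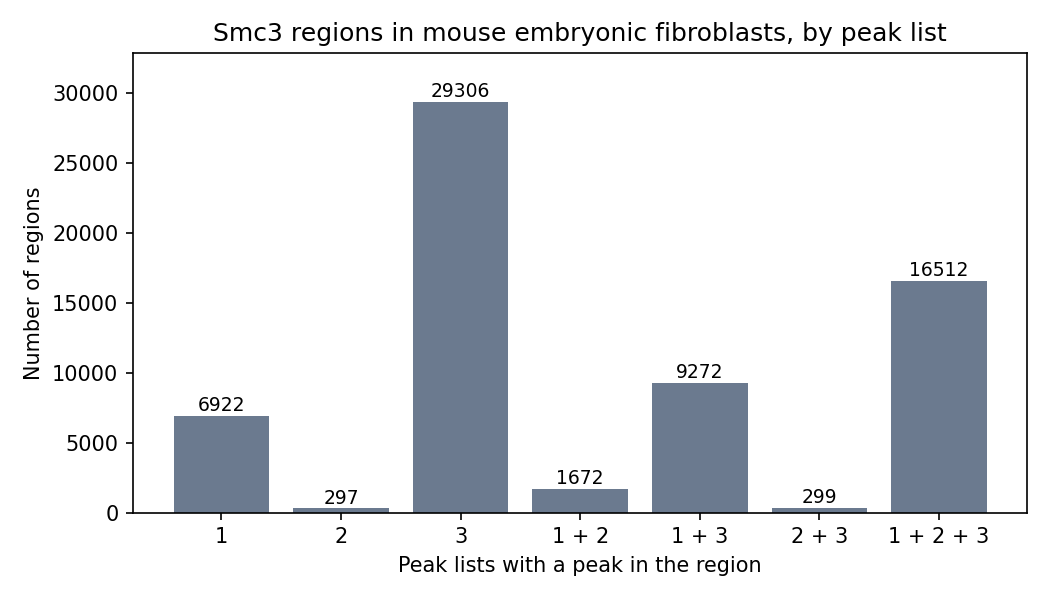
Number of Smc3 regions (vertical axis) by the peak lists that have a peak in the region (horizontal axis), in mouse embryonic fibroblasts. The bar of list 3 alone (29306 regions) is the tallest, followed by that of all 3 lists (16512).

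The shortest list was almost contained in the others. Of the list 2 regions, 98.4% held a peak of another list and 87.9% held peaks of both. The shares with another list were 79.9% for list 1 and 47.1% for list 3. Counted by peaks, 96.4% of list 2 peaks overlapped a list 1 peak, against 1.18% ± 0.08 (SD of 100 draws) when list 1 peaks were moved by 10 to 100 kb. Of list 1 peaks, 76.1% overlapped a list 3 peak, against 2.55% ± 0.08 after moving. Of list 3 peaks, 46.8% overlapped a list 1 peak and 30.2% a list 2 peak, against 1.68% and 0.799% after moving. In each of the 6 ordered pairs of lists the observed overlap exceeded the highest of the 100 draws. The highest moved overlap in any pair was 2.74%.

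Where 2 lists had 1 peak each in a region, these peaks overlapped or were joined through peaks of the third list. The way regions were joined thus limits how far apart their midpoints can lie. The median distance between midpoints was 20 bp for lists 1 and 2 over 17243 regions, and 95% of these distances were at most 76 bp. It was 35.5 bp for lists 1 and 3 over 24341 regions, and 35.5 bp for lists 2 and 3 over 16314 regions, with 95% of distances at most 153.5 and 153 bp. The median peak width was 211 bp in list 1, 196 bp in list 2 and 244 bp in list 3.

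Shared regions held wider peaks in every list. In list 1 the median peak width was 146 bp in regions of that list alone, 181 bp in regions of 2 lists and 263 bp in the core. The same medians were 133, 153 and 203 bp in list 2, and 192, 273 and 374 bp in list 3. The narrowest width a list contains was 114 bp in list 1, 117 bp in list 2 and 154 bp in list 3. Of the list 3 peaks in no other list, 19.8% had exactly that narrowest width, against 0.744% of its peaks in the core. For list 1 these shares were 16.9% and 0.981%. Across regions, Spearman's rho between the score and the width of the region was 0.66. Regions are not replicates, and a union of several peaks is wider by construction, so this value carries no test. Within lists 1, 2 and 3, rho between the width of a single peak and the number of lists in its region was 0.60, 0.27 and 0.57.

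**Figure D2:**
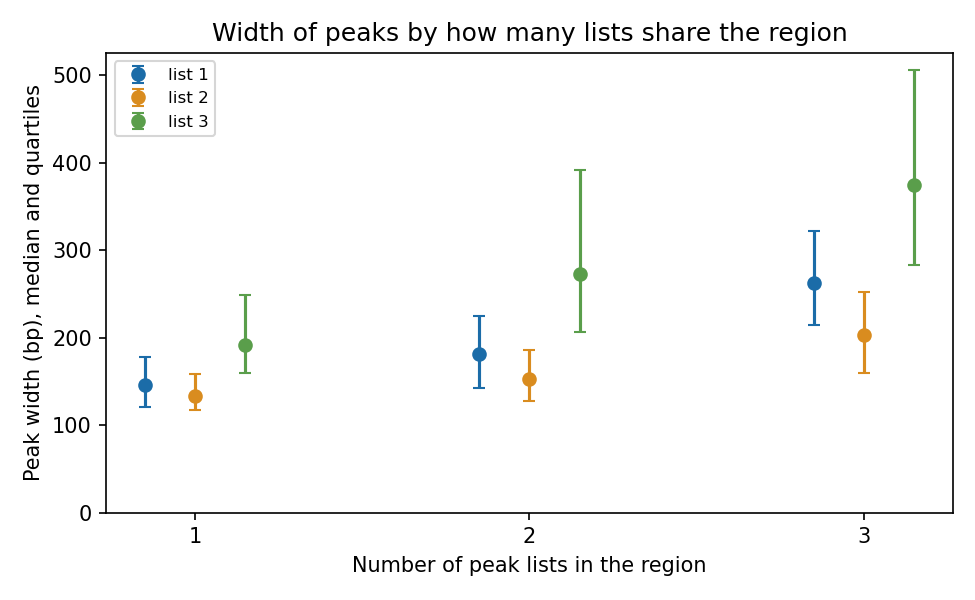
Width in bp of the peaks of each list (median, with bars from the first to the third quartile) by the number of lists with a peak in the region. The medians of list 1 go from 146 to 263 bp, those of list 2 from 133 to 203 bp and those of list 3 from 192 to 374 bp.

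Smc3 regions were narrow. The median region width was 237 bp, with quartiles of 172 and 356 bp, and 956 regions (1.49%) were wider than 1 kb. Core regions had a median of 393 bp. The 5 widest regions all held peaks of the 3 lists. The widest lay on chromosome 19 from 5835177 to 5846041 and was 10865 bp long, and 1 list 1 peak of 10410 bp, the widest of that list, spanned nearly all of it. List 2 had 16 peaks there and list 3 had 5. The next were a region of 5778 bp on chromosome 10 (36855621 to 36861398), one of 5427 bp on chromosome 11 (94806566 to 94811992), one of 5036 bp on chromosome 2 (117941160 to 117946195) and one of 4558 bp on chromosome 11 (86392363 to 86396920). These 5 regions held between 6 and 22 peaks each.

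Neighbouring Smc3 regions lay closer together than uniform random positions. Those positions could also fall in sequence that cannot be mapped, where no region can be called. Gaps over 1 Mb between regions took up 11.1% of the span of all chromosomes. How much of the difference in spacing this accounts for was not tested. The median distance between midpoints was 11.8 kb (quartiles 2.49 and 35.4 kb), against 26.1 kb for random placements, whose medians ranged from 25.8 to 26.5 kb. Of all neighbours, 46.7% were under 10 kb apart, against 23.5% at random. Core regions had a median distance of 58.1 kb (quartiles 18.99 and 142.2 kb), against 101.8 kb at random. Of core neighbours, 16.4% were under 10 kb apart, against 6.68% at random. The distance depends on how many regions are counted: it was 26.9 kb in list 1, 54.8 kb in list 2 and 12.9 kb in list 3, or 31.5 ± 21.4 kb (SD, n = 3). It was 23.9 kb for the union without list 3 and 18.0 kb when regions within 1 kb of each other were merged.

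**Figure D3:**
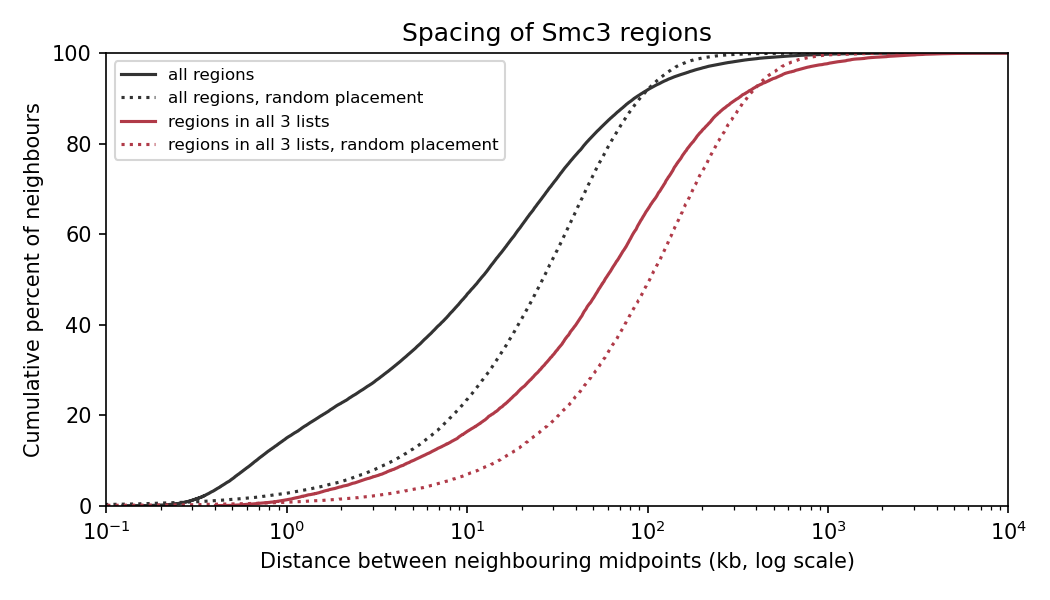
Cumulative percent of neighbouring regions (vertical axis) within a distance between midpoints in kb (horizontal axis, log scale), for all regions and for the regions in all 3 lists, with 1 random placement of each as dotted lines. The observed medians, 11.8 and 58.1 kb, lie to the left of the random medians of 26.1 and 101.8 kb.

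Smc3 regions were unevenly spread at the scale of 1 Mb. Over 2582 windows of 1 Mb the mean was 24.9 regions, 4.57% of windows held none and the fullest held 160. The variance of regions per window was 22.6 times the mean, against 3.04 on average and 3.14 at most in 1000 random placements, which keep the number on each chromosome (one-sided permutation of positions, p = 0.001, the smallest these placements can give). The ratio was 5.997 for core regions, against 1.58 at most at random, and 11.6 for the union without list 3. The overdispersion, which unlike this ratio does not grow with the number of regions, was 0.74 in list 1, 0.64 in list 2 and 0.99 in list 3, or 0.79 ± 0.18 (SD, n = 3). The numbers of regions per window were correlated between lists: across 2420 autosomal windows, Spearman's rho was 0.95 for lists 1 and 2, 0.95 for lists 1 and 3 and 0.92 for lists 2 and 3, with Pearson's r of 0.94, 0.95 and 0.90. Windows are not independent replicates. As for spacing, the random placements could fall in sequence that cannot be mapped, and how much of the unevenness this accounts for was not tested.

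The fullest windows were neighbours on chromosome 10. The window from 80000001 to 81000000 held 160 regions, 40 of them in the core, and the window from 79000001 to 80000000 held 155, with 39 in the core. A window on chromosome 19 (5000001 to 6000000), which contains the widest region, held 152, with 42 in the core. These 3 windows were also the 3 fullest of each list. The others were on chromosome 2 (30000001 to 31000000, 147 regions, 21 in the core) and on chromosome 7 (52000001 to 53000000, 142 regions, 27 in the core). The chromosome 2 window ranked 4 in list 3, 8 in list 1 and 99 in list 2.

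The longest stretches without a region were on X. They ran from 113478392 to 125838595 (12.4 Mb) and from 23270511 to 33374506 (10.1 Mb). The next 3 were on chromosome 7, with 7.38 Mb from 39052402 to 46437230, 4.21 Mb from 20542187 to 24753170 and 3.45 Mb from 7252520 to 10700241. Gaps over 1 Mb took up 46.0% of the span of X (28 gaps) and 8.82% of that of the autosomes (134 gaps). Which part of them could not be mapped was not analysed here.

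Chromosome 11 was the densest chromosome and X by far the sparsest. Chromosome 11 had 42.2 regions per Mb and chromosome 19 had 35.3, while the sparsest autosome, chromosome 3, had 20.7. The autosomes had 26.7 ± 5.42 regions per Mb (SD over 19 autosomes) and X had 5.52, or 0.21 times the autosomal mean. X was the lowest of the 20 chromosomes, and none of the others lay as far from their median density in either direction (exact two-sided p = 0.05, the smallest that 20 chromosomes allow). No region was listed on Y. Chromosome 11 was the densest and X the sparsest in each of the 3 lists and in the core, where they had 10.4 and 1.37 regions per Mb. With gaps over 1 Mb left out of all lengths, the X to autosome ratio was 0.35. Those gaps are defined by the same regions and took up more of X, so leaving them out raises the ratio by construction.

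**Figure D4:**
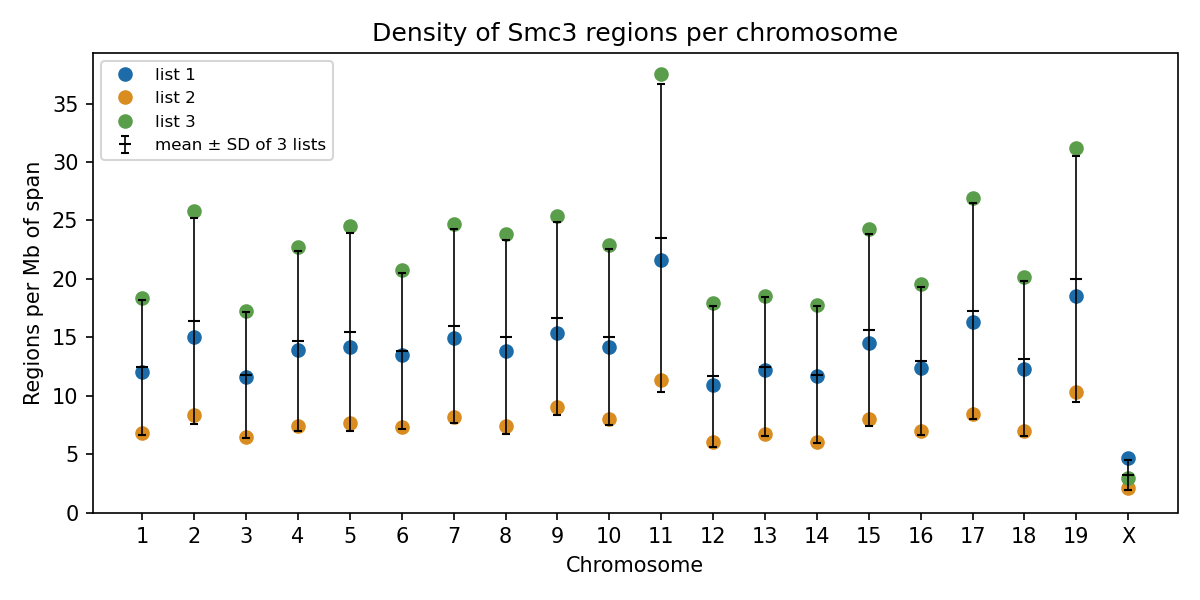
Smc3 regions per Mb of span (vertical axis) on each mouse chromosome (horizontal axis) for the 3 peak lists, with the mean and SD of the lists in black. Chromosome 11 is the highest and X the lowest in each list; on X, list 1 (4.64 per Mb) lies above list 3 (2.93 per Mb), against the order on the autosomes.

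The 3 lists differed in how sparse X was. The X to autosome ratio was 0.33 in list 1, 0.27 in list 2 and 0.13 in list 3, or 0.24 ± 0.10 (SD, n = 3), and 0.32 in the union without list 3. List 3 had more regions than list 1 on each autosome but fewer on X, where it had 471 against 745. Regions of list 1 alone made up 34.7% of the regions on X (31.6 to 37.8%, Wilson) and 10.4% of those on autosomes (10.2 to 10.7%). Regions of list 3 alone made up 13.8% on X (11.7 to 16.2%) and 46.0% on autosomes (45.6 to 46.4%). The intervals of the share of core regions overlapped, with 24.8% on X (22.1 to 27.8%) and 25.7% on autosomes (25.4 to 26.0%). Of the regions in both lists 1 and 2, list 3 also held 70.5% on X (65.2 to 75.3%, 220 of 312) and 91.2% on autosomes (90.7 to 91.6%, 16292 of 17872). The same test of list 2 gave 63.6% on X (58.4 to 68.5%) and 64.0% on autosomes (63.5 to 64.6%), and that of list 1 gave 98.7% on X (96.1 to 99.5%) and 98.2% over 16588 autosomal regions. These tests of lists 1 and 2 cover only sites that list 3 called. Over all list 1 regions, list 2 also held fewer on X, with 41.9% (38.4 to 45.5%) against 53.1% on autosomes (52.6 to 53.7%). List 3 held 46.4% (42.9 to 50.03%) of them on X against 75.6% on autosomes (75.2 to 76.1%). Over all list 2 regions, list 1 held 94.3% on X (91.2 to 96.3%) against 96.9% on autosomes (96.6 to 97.1%). Of the same list 2 regions, list 3 held 67.4% on X (62.1 to 72.2%) against 89.9% on autosomes (89.5 to 90.3%). Over all list 3 regions the order was the other way. List 1 held 73.5% of these on X against 46.3% on autosomes, and list 2 held 47.3% against 30.2%.

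**Figure D5:**
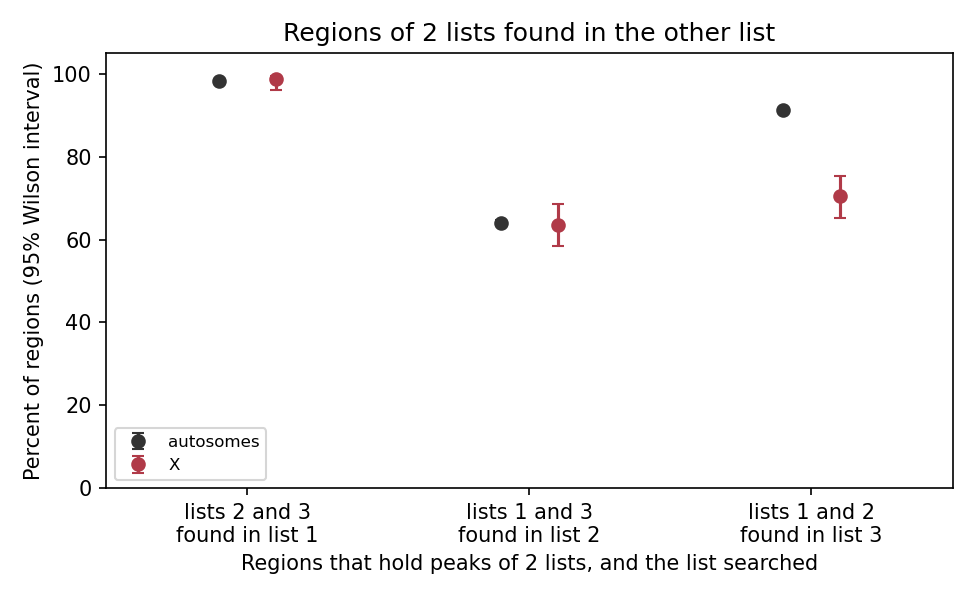
Percent of the regions with peaks of 2 lists that also hold a peak of the other list (vertical axis), on the autosomes and on X, with 95% Wilson intervals. On X, list 3 holds 70.5% of the regions of lists 1 and 2, below its 91.2% on autosomes; for lists 1 and 2, searched only at sites that list 3 called, the intervals on X include the autosomal value.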

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

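The alternatives with thresholds of 2 or 3 lists, with lists taken singly, with gaps left out and with a minimum overlap, and the results on regions in all 3 lists and on overdispersion, were chosen after seeing the data; the others were chosen before. Of the 55 alternatives, 10 were counted as moving a result by more than the spread between lists or a count by over 1.5 times. None of the 10 concerns the variance to mean ratio, whose SD between lists was 8.48 (n = 3). That ratio changed by more than this with at least 2 lists (9.52), in the core and without list 3. It also did so in windows of 200 kb and 5 Mb. The number of regions, 64280, came to 52488 when regions within 1 kb were merged, 27755 with peaks of at least 2 lists and 16512 with peaks of all 3. With each list left out in turn it ranged from 36696 (without list 3) to 64018 (without list 2). Requiring a common stretch of 1, 50 or 100 bp left 16450, 16374 and 15956 of the 16512 regions in all 3 lists. The median width of 237 bp became 350 bp in regions of at least 2 lists and 393 bp in the core. The median spacing of 11.8 kb became 11.5 kb edge to edge, 18.0 kb with regions within 1 kb merged, 32.4 kb in regions of at least 2 lists, 58.1 kb in the core and 23.9 kb without list 3. The X to autosome ratio of 0.21 ranged from 0.15 (without list 1) to 0.32 (without list 3), was 0.33, 0.27 and 0.13 in lists 1, 2 and 3 by themselves and was 0.35 with gaps over 1 Mb left out of the lengths, where the shorter length of X is the cause by construction. The variance to mean ratio of 22.6 was 7.69 in windows of 200 kb, 63.1 in windows of 5 Mb, 11.6 without list 3 and 5.997 in the core, each above all 1000 random placements made the same way. The overdispersion was 0.87 for all regions and 0.78 for the core. The relation of peak width to sharing was lower within list 2 (rho 0.27) than within lists 1 and 3 (0.60 and 0.57). The 0.66 across regions is for score and region width, which is another measure. Of the 19321 list 2 peaks, 17051 lay in core regions, so sharing varied little within that list. How far this lowered rho was not tested. Of the 3 lists, leaving out list 3 moved the number of regions, their spacing and the X ratio the most. No paired analysis was possible because a single group was analysed. The planned threshold at the median score, the merging of overlapping regions and the restriction to chromosomes 1 to 19 and X removed nothing and so test nothing. They are nevertheless counted among the 55 alternatives. The alternatives on assembled length, genes and motifs were not run. Without read counts per peak, a region missing from a list cannot be told from one that its depth did not reach.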

Other observations

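Regions of 1 list lay nearer to core regions than positions drawn at random within the same 1 Mb windows. The 29306 regions of list 3 alone lay at a median of 24.0 kb from the nearest core region, against 35.3 kb for drawn positions (34.4 to 35.9 kb in 100 draws). Within 10 kb of a core region lay 29.7% of them, against 19.8% of drawn positions and 20.4% at most. The 6922 regions of list 1 alone had a median distance of 31.4 kb, against 44.0 kb for drawn positions, and 25.2% of them lay within 10 kb of a core region, against 16.9%. For the 297 regions of list 2 alone the median was 54.4 kb, against 68.4 kb for drawn positions (56.2 to 83.3 kb). The set and its distances were chosen after the data were seen.

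The shortage of X regions in list 3 was noticed in the data, and the tests of it were set only then, each with its prediction written before its own result was seen. List 3 held 0.63 times as many regions as list 1 on X, but 1.63 times as many on the autosomes. A chromosome that is merely sparse does not account for this: autosomal windows of 1 Mb with the same numbers of list 1 regions as the 162 windows of X gave ratios from 1.37 to 1.87 in 1000 draws. Narrower sites on X, as measured by list 1 peak width, left part of the shortage unaccounted for. The list 1 peaks of regions shared by lists 1 and 2 had a median width of 210.5 bp on X and 260 bp on autosomes. Autosomal regions matched on that width were found in list 3 in 85.6% of cases on average and 79.5% at the lowest. Both values lie above the upper bound of 75.3% on X. This matching used list 1 width alone, so it cannot exclude that X sites were weaker in ways that this width does not show. List 3 held 70.5% of the X regions of lists 1 and 2, below the lowest autosome, chromosome 16, with 86.4% (83.5 to 88.8%, Wilson), but this does not tell a site that list 3 failed to call from one that was not bound. A lower signal of list 3 along X predicts narrower peaks also at the sites it holds. In the 220 core regions on X, list 3 peaks were a median of 1.17 times as wide as list 1 peaks, against 1.34 to 1.60 times in 1000 draws of autosomal core regions matched on list 1 width. A lower signal along X in the list 3 library, whether from fewer X reads or from weaker binding, predicts such a lower ratio. The ratio was taken against list 1 only, so a higher list 1 signal on X would lower it too. Width stands in for signal here, since no read counts were used.

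In 3 parts of X of equal length, from the start to the end of its span, list 3 held 74.2% (64.7 to 81.9%), 75.9% (67.1 to 83.0%) and 61.7% (52.2 to 70.3%) of the regions of lists 1 and 2. Each interval lies below the 91.2% of the autosomes and below 85.6%, the mean of the width-matched draws for the whole of X. Only that of the last part lies below 79.5%, the lowest of those draws. The draws were matched to the whole of X and not to each part. They therefore cannot decide how much of the shortage narrow sites account for in a single part. A hypothesis is that the cells of the list 3 library carried fewer copies of X per autosome set than those of the others, as cells of a male embryo would, which may lower the read depth along X and with it the 70.5% found. It was not tested, since the labels give no sex. The number of reads per Mb on X and on Y in each library would test it, and read counts were not used here. No region was listed on Y, or on any sequence other than chromosomes 1 to 19 and X, in any list; whether Y was searched is not given in the sources used here. A difference between the lists in control library or calling settings stays open as well, and no biological explanation was tested. List 2 also held fewer list 1 regions on X than on autosomes, 41.9% against 53.1%. List 1 held fewer list 2 regions on X, 94.3% against 96.9%. The causes were not tested.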
